A study of Homo sapiens with 12 samples.

How the data were processed

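The series holds 12 RNA-seq libraries of SUM159 cells, a human mammary carcinoma line, from a subline named for high ITGB4 (integrin beta 4). Cells with a non-targeting guide (NT) and cells with CRISPR knockouts of p63 (p63KO), of p73 (p73KO) and of both (dKO) gave 3 libraries each, described as biological triplicates in the series' design text. Polyadenylated RNA was captured and made into libraries with a KAPA mRNA HyperPrep kit, which marks strand with dUTP, per the labels' protocols.

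The deposited values are raw counts, whole numbers per Ensembl gene, with 1 file per library and 58243 genes in each. Reads were checked with FastQC, whose version is not given, and aligned with STAR 2.5.4b to hg38 (GRCh38), per the submitters' processing notes. The tool that counted reads, its strand setting and its gene annotation are not given in the sources used here. A gene that overlaps another on the opposite strand may therefore hold some of its reads, and genes with near-identical copies may share theirs. Each file held 1 row per gene and 0 rows that were not genes. Names and coordinates came from GENCODE 29 on GRCh38, which matched 57980 of the gene identifiers by identifier; with a table of gene names, 42284 had a symbol or name.

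The total count per library was between 20110899 and 30081764. No library was a copy of another of its group. Between libraries of a group, the chi-square per degree of freedom over genes with at least 20 counts ran from 10.138 to 41.123. Replicates thus varied more than counting error alone allows. Intervals and floors given for genes with few counts cover counting error only. The floor is 3 counts summed over the libraries of a group.

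Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings by group, which left 14754, and libraries were scaled by TMM. A single negative binomial model with a mean per group was fitted to all 12 libraries (8 residual degrees of freedom, biological coefficient of variation 12.4%), and each comparison was tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene counts as called, or as having risen or fallen, when its adjusted p was under 0.05. The comparisons were each knockout against NT, dKO against each single knockout, p63KO against p73KO, and the interaction (dKO minus p63KO minus p73KO plus NT on the log2 scale). Every adjusted p for a gene is from this test unless another is named. Fold changes are log2 with standard errors (SE) derived from the F statistic. Levels are counts-per-million (CPM) of the TMM-scaled library size, computed here from the deposited counts, as mean ± SD of 3 libraries.

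The replicate numbers in the labels are not stated to pair the groups. Whether they do was checked in the data: after each group's mean was removed, the 18 correlations across genes between libraries of different groups with the same number ran from 0.212 to 0.585, each above the minimum of 0.1 set for pairing, and the 36 between different numbers ran from -0.452 to 0.162. For all 12 libraries, the most correlated library in each of the other groups had the same number. The pairing thus comes from the data and not from the labels. A fit with the number as a block (6 residual degrees of freedom, coefficient of variation 6.79%) is given beside a result where it changes a call or moves a count by more than 1.5 times.

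The comparisons, tests, rule for named genes, 22 gene lists and main alternatives were fixed before the data were examined. The rule named TP63, TP73 and ITGB4 in every comparison. Some genes it named and 1 list are not reported here. It also took the 8 largest increases and the 8 largest decreases in each knockout against NT, and the 4 largest of each in the other comparisons. These came from called protein-coding genes with a mean of at least 2 CPM whose libraries did not overlap between the groups; the last condition was not asked of the interaction. From each list it took up to 4 called members per knockout with the largest change. Values of a list member named in one knockout are given for all 3 unless a single knockout is stated, and ACTA2, SNAI1, SNAI2, AXIN2, FZD8, LAMA3, DST, CD151, CDKN1A, TNFAIP2 and WRAP73 were chosen after their values were seen. The lists were basal keratinocyte genes, hemidesmosome with laminin-332 and epithelial integrins, EGFR family ligands and receptors, ERK pathway output, wound-edge keratinocyte genes, epithelial and luminal genes, mesenchymal genes, p53 target genes, proliferation genes, interferon response, NF-kB and inflammatory cytokines, YAP and TEAD targets, TGF-beta response, Notch pathway, Wnt pathway, multiciliated cell genes, hypoxia response, cholesterol synthesis, integrated stress and unfolded protein response, mitochondrially encoded genes, and markers of other cell types. Of their 453 genes, 452 were matched, and 15 were in 2 or more lists. Several lists were tested in part, since members under the low-count filter were left out. Tested were 15 of 28 basal keratinocyte, 15 of 28 wound-edge, 9 of 24 epithelial and luminal and 7 of 20 multiciliated genes.

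Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with a correlation estimated per list. Members were counted as called over all genes tested and adjusted over the list alone. Fry was run as an alternative; it does not compare a list with other genes.

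The 3 comparisons against NT share their NT libraries, which makes their fold changes correlated without any effect. Beside each overlap of 2 comparisons stand the number for independent comparisons and the values from 20 simulations of unchanged groups with shared controls. Genes varied independently in these simulations, so the spread of their covariances may be too narrow. With 3 NT libraries the controls could not be divided between comparisons, so part of the excess over independent comparisons may come from the shared controls. Principal components used log2 CPM with a prior count of 2.

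The scripts were tested on simulated data with known changes, drawn from the real means and library sizes. For p63KO against NT (14535 genes), 35.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold were called, and 4.79% of 146 calls were false. For the interaction (14526 genes), the percentages called were 11.9%, 49.3% and 80.3%, and 9.62% of 104 calls were false. A list of 30 genes shifted by 0.5 log2 was called by camera and 0 of 20 unchanged lists were (14517 genes). Simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely.

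Alternatives were RLE size factors, no low-count filter, a robust prior, the DESeq2 1.42.0 Wald test, a fit of the 2 compared groups only, the replicate block, an adjusted p under 0.01, and each library left out in turn. Leaving out the libraries numbered 3 from every group was chosen after the data were seen. The fits with libraries left out did not include the replicate block, so they do not take the pairing by number into account. Read sequences, guide sequences and cut sites were not analysed here, so editing itself was not examined.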

Results

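Gene expression was measured in 12 libraries of SUM159 mammary carcinoma cells of an ITGB4-high subline: 3 with a non-targeting guide (NT), 3 with a p63 knockout (p63KO), 3 with a p73 knockout (p73KO) and 3 with both (dKO). p63 and p73 are transcription factors of the p53 family, and the series asks what each controls in these cells. The files held between 20110899 and 30081764 counts per library (median 26171172) and between 21806 and 23289 genes with a count. Genes of the mitochondrial chromosome took 3.85% to 5.65% of the counts, the highest share being that of p63KO replicate 2, and the 10 most abundant genes of a library took 4.59% to 6.25%.

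TP63, the gene of p63 (ENSG00000073282, chromosome 3, 189631416 to 189897279, GRCh38), stood at 192 ± 65.4 CPM in NT (SD, n = 3), 48.7 ± 16.6 CPM in p63KO, 28 ± 10.9 CPM in p73KO and 24.1 ± 8.36 CPM in dKO. TP73, the gene of p73 (ENSG00000078900, chromosome 1, 3652520 to 3736201), stood at 6.37 ± 0.417, 1.42 ± 0.256, 1.8 ± 0.331 and 1.22 ± 0.226 CPM in the same order. Each of the pair thus fell in its own knockout and also in the knockout of the other. TP63 fell by 1.97 log2 in p63KO (SE 0.346, adjusted p = 0.000917), by 2.78 in p73KO (SE 0.36, adjusted p = 7.13e-05) and by 2.99 in dKO (SE 0.363, adjusted p = 3.68e-05). TP73 fell by 2.17 in p63KO (SE 0.198, adjusted p = 3.23e-06), by 1.83 in p73KO (SE 0.195, adjusted p = 1.27e-05) and by 2.37 in dKO (SE 0.201, adjusted p = 1.33e-06). Counts over the whole gene cannot show whether the remaining transcripts encode protein: TP63 kept 25.4% of its NT level in p63KO, and TP73 kept 28.2% in p73KO. ITGB4, the integrin the subline is named for (ENSG00000132470, chromosome 17, 75721328 to 75757818), fell from 540 ± 33.5 CPM to 24 ± 8.82, 32.7 ± 18.7 and 21.2 ± 7.03 CPM, which was 22.6-fold, 16.4-fold and 25.4-fold. TP73 lies over WRAP73 on the opposite strand, whose mean level was 6.96 times that of TP73. With the strand setting of the counting not given, some TP73 counts may be reads of WRAP73, so the residual level is uncertain.

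**Figure D1:**
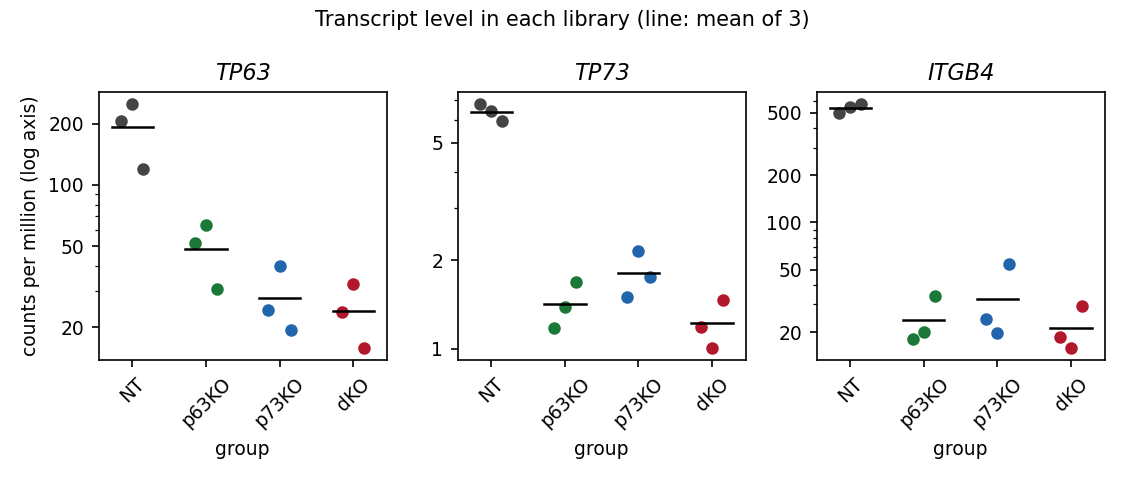
Level in CPM (log axis) of TP63, TP73 and ITGB4 in each of the 12 libraries, by group; points are libraries and lines the means of 3. They are lower in every knockout library than in every NT library.

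The libraries separated mainly into NT and knockouts. Principal component 1 held 61.5% of the variance and placed the 3 NT libraries between -74.63 and -66.92 and the 9 knockout libraries between 13.89 and 30.73. Component 2 (12.5%) placed the library numbered 3 of every group below those numbered 1 and 2. Across genes, log2 CPM correlated at 0.9474 to 0.9669 between NT and knockout libraries, at 0.9815 to 0.9941 between libraries of different knockouts and at 0.9845 to 0.9938 within groups. All edited lines were compared with 1 non-targeting line, so a difference of that line for another reason would appear in each comparison with NT.

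**Figure D2:**
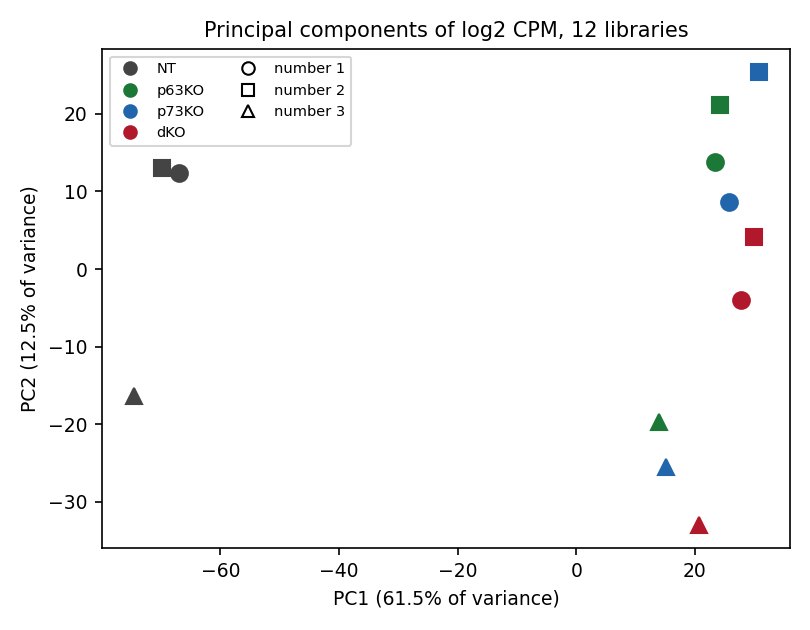
Principal components 1 (61.5% of the variance) and 2 (12.5%) of log2 CPM; colours are groups and symbols the replicate numbers. NT lies apart from the 9 knockout libraries on component 1, and the number 3 library is the lowest of its group on component 2.

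What p63 loss changes was asked by p63KO against NT. TGFA, a ligand of the EGF receptor, fell from 68.8 ± 6.57 to 0.531 ± 0.0674 CPM (128-fold, log2 -7.00, SE 0.181, adjusted p = 9.5e-11). CSF3, the granulocyte colony-stimulating factor, fell 135-fold from 39 ± 12.1 CPM, and the phospholipase gene PLCH2 fell 229-fold from 39.9 ± 11.7 CPM. In the other direction, MSTN (myostatin) had 0 counts in NT and 301 in p63KO, at least 97.5-fold higher against the floor of 3 counts. COL5A3, a fibrillar collagen chain, rose from 0.0573 ± 0.0688 to 9.11 ± 1.75 CPM (log2 7.28, SE 0.599, adjusted p = 1.33e-06). Of 14754 genes tested, 4073 were called, 2213 higher and 1860 lower, of which 802 and 606 changed at least 2-fold. With the replicate block 6792 were called. Further large increases were those of the procollagen enhancer PCOLCE (115-fold), the Hedgehog pathway transcription factor GLI2 (77.5-fold) and the kinase gene CDK15 (72-fold, from 0.342 ± 0.173 to 24.5 ± 5.05 CPM). APCDD1, a Wnt inhibitor, had 1 count in NT and a ratio of 214 (95% counting interval 38 to 8480), LRRC7 had 3 and a ratio of 106 (35.8 to 515), and the chemerin receptor gene CMKLR1 had 0 and was at least 35.6-fold higher. Further large decreases were those of PPP1R14C (187-fold), xanthine dehydrogenase XDH (41.8-fold), PHEX (36.4-fold), the calcium channel subunit gene CACNB4 (27.9-fold) and IGFBP2 (23.7-fold). MSTN and LRRC7 overlap other genes on the opposite strand, so part of their counts may come from those.

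What p73 loss changes was asked by p73KO against NT. TGFA fell to 0.334 ± 0.165 CPM (208-fold, log2 -7.70, SE 0.195, adjusted p = 5.47e-11). CSF3 was left with 3 counts against 2957 in NT, a ratio of 932 (95% counting interval 318 to 4520). ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, fell from 113 ± 25.7 to 1.89 ± 0.534 CPM (60.8-fold, log2 -5.93, SE 0.251, adjusted p = 4.85e-09). CDH6, a cadherin, rose from 1.39 ± 0.85 to 87.6 ± 17.9 CPM (64.6-fold, log2 6.01, SE 0.302, adjusted p = 1.67e-08), and DKK1, a secreted Wnt inhibitor, rose 65.7-fold to 11.8 ± 5.48 CPM. Of the 14754 genes 4638 were called, 2524 higher and 2114 lower, of which 906 and 559 changed at least 2-fold. With the replicate block 7142 were called. PCOLCE (91-fold) and GLI2 (68.5-fold) also rose. MSTN was at least 67-fold and CMKLR1 at least 45.8-fold higher, and the ratio was 377 (67.2 to 14900) for APCDD1 and 71.2 (24 to 348) for LRRC7. PPP1R14C (369-fold), PLCH2 (139-fold), XDH (62.5-fold), the hemidesmosome collagen COL17A1 (41.3-fold) and the homeobox gene CUX2 (39.8-fold) fell.

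What the loss of both changes was asked by dKO against NT. ALDH1A1 fell to 0.754 ± 0.29 CPM (150-fold, log2 -7.23, SE 0.277, adjusted p = 1.45e-09), CUX2 from 54 ± 2.07 to 0.544 ± 0.0346 CPM (98.1-fold) and ENKUR from 44.1 ± 10.2 to 0.582 ± 0.272 CPM (74.9-fold). TGFA fell 138-fold to 0.495 ± 0.0104 CPM. CMKLR1, with 0 counts in NT and 465 in dKO, was at least 147-fold higher, and MSTN at least 111-fold. Of the 14754 genes 3809 were called, 2086 higher and 1723 lower, of which 847 and 577 changed at least 2-fold. With the replicate block 6351 were called. Increases also included PCOLCE (121-fold), COL5A3 (101-fold), CDK15 (79.7-fold) and GLI2 (76-fold), with ratios of 350 (62.5 to 13900) for APCDD1 and 120 (40.9 to 586) for LRRC7. Decreases included PLCH2 (302-fold), PPP1R14C (243-fold), CSF3 (214-fold) and XDH (118-fold). ENKUR and THNSL1 overlap on opposite strands, so part of the ENKUR counts may be reads of THNSL1.

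Mesenchymal genes rose together in each knockout. Of 29 tested members, 25 rose and 1 fell in p63KO, in p73KO and in dKO, and 3 did not pass in each; adjusted over the list alone the counts were 25 and 1, 25 and 1, and 25 and 2, and with the replicate block 2 fell in each. The collagen gene COL5A1 rose from 32.9 ± 4.44 CPM to 503 ± 30.2, 594 ± 23.4 and 755 ± 31.1 CPM (log2 3.93, 4.17 and 4.52). The growth factor receptor gene PDGFRB rose from 0.624 ± 0.317 to 12.7 ± 1.39, 14.2 ± 2.04 and 21.9 ± 2.15 CPM, and the collagen genes COL3A1 (log2 5.06, 4.02 and 5.21) and COL6A2 (log2 4.05, 3.37 and 4.59) rose too. ACTA2, smooth muscle actin, was the member that fell (log2 -1.48, -2.12 and -1.90). SNAI1 and SNAI2, transcription factors of the epithelial-mesenchymal transition, did not pass: the log2 values of SNAI2 were -0.48, -0.64 and -0.90, which passed with the replicate block. Camera called the list up with an estimated correlation as well (adjusted p = 7.55e-05, 7.06e-05 and 4.31e-05). Of the markers of other cell types, PDGFRA and DCN of fibroblasts fell beside these genes, PDGFRA from 90.7 ± 41.6 to 6.98 ± 0.465, 10.1 ± 0.872 and 9.06 ± 0.827 CPM.

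Wnt pathway genes also rose. Of 16 tested, 12 rose in each knockout; 0 fell in p63KO by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, 1 with the replicate block) and 1 in p73KO and dKO. Adjusted over the list alone, 12 rose and 1 fell in each. WNT5A rose from 0.666 ± 0.484 CPM to 13.6 ± 0.207, 12.1 ± 1.76 and 21.5 ± 2.22 CPM (log2 4.38, 4.22 and 5.04). The Wnt inhibitors NKD2 (log2 4.29, 4.16 and 5.25) and DKK1 (log2 5.52, 6.04 and 5.90) and the ligand WNT7B (log2 4.80, 3.90 and 5.08) rose as well, and so did AXIN2, a target of the pathway (log2 1.14, 1.31 and 1.15). Camera called the list up, with adjusted p = 0.00069, 0.00356 and 0.000814 with an estimated correlation. The 1 lower call, FZD8, was lost in p73KO without NT replicate 1 or 3 or p73KO replicate 1 or 2, and in dKO without NT replicate 1, 2 or 3 or dKO replicate 1 or 2, which left 0.

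Genes that attach basal epithelial cells to the basement membrane mostly fell. Of 16 tested members of the hemidesmosome, laminin-332 and epithelial integrin list, 9 fell, 3 rose and 4 did not pass in each knockout (lower 10, 9 and 9 and higher 3, 3 and 3 adjusted over the list alone; higher 5, 4 and 5 with the replicate block). Beside ITGB4, the laminin chain gene LAMB3 fell from 127 ± 22.1 to 18.6 ± 1.12, 22.6 ± 3.2 and 21.7 ± 0.808 CPM. COL17A1 fell as well (log2 -4.30, -5.37 and -5.56). LAMA3, another chain of laminin-332, rose (log2 1.13, 1.17 and 1.24), as did DST and CD151; without NT replicate 3, 1 member rose in p63KO. Camera called the list down in each knockout; with an estimated correlation the adjusted p was 0.0453 in p63KO, 0.055 in p73KO and 0.0497 in dKO, and 0.0275, 0.0179 and 0.0211 with the block as well.

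Basal keratinocyte genes, many of them known targets of p63 in squamous epithelium, had 15 tested members out of 28. In each knockout 9 of them fell, and 1, 1 and 2 rose in p63KO, p73KO and dKO (9 lower in each and 2, 1 and 2 higher adjusted over the list alone). The S100 protein gene S100A2 fell from 127 ± 26.5 CPM to 20.8 ± 1.38, 25.3 ± 8.25 and 23.2 ± 3.19 CPM. CSTA, a protease inhibitor of keratinocytes, fell from 61.1 ± 5.57 to 11.7 ± 1.71, 9.68 ± 0.46 and 8.72 ± 1.09 CPM. KRT6A, which may share reads with KRT6B and KRT6C, was left with 1, 3 and 2 counts against 155 in NT, ratios of 160 (28.2 to 6340), 48.8 (16.4 to 239) and 81.6 (22.2 to 680). The call of the list by camera (adjusted p = 1.26e-05, 6.64e-06 and 1.38e-06) was lost with a correlation estimated from its members: adjusted p = 0.198, 0.235 and 0.185 with an estimated correlation, and 0.0465, 0.0179 and 0.0304 with the block as well. With the block 3 members rose in p63KO.

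EGFR family ligands and ERK pathway output fell in part. Of 11 tested EGFR ligands and receptors, 4 fell, 2 rose and 5 did not pass in each knockout (lower 4 in each and higher 2, 3 and 2 adjusted over the list alone; higher 4, 4 and 5 with the replicate block). Beside TGFA, amphiregulin AREG fell from 231 ± 86.5 CPM to 16.9 ± 2.59, 22.2 ± 2.72 and 13.6 ± 2.96 CPM, and epiregulin EREG from 1249 ± 292 to 276 ± 64.4, 233 ± 47.7 and 209 ± 47.5 CPM. Neuregulin NRG1, a ligand of ERBB3 and ERBB4, rose from 3.95 ± 1.18 to 60.5 ± 14.9, 79.4 ± 29.7 and 70.5 ± 15.7 CPM. The median of the list was -0.0518, 0.21 and 0.223 log2 and its mean -0.714, -0.706 and -0.733, so median and mean differed in sign in p73KO and dKO; camera called it down, with adjusted p = 0.0649, 0.0964 and 0.0803 with an estimated correlation, and 0.0295, 0.0338 and 0.0355 with the block as well. Of 16 genes of ERK pathway output, 8, 7 and 8 fell and 1, 2 and 1 rose (lower 8, 8 and 9 and higher 2, 2 and 2 adjusted over the list alone; higher 2 in p63KO and in dKO with the block). The ERK phosphatase gene DUSP6 fell from 72.8 ± 2.39 to 10.8 ± 1.79, 12.6 ± 0.49 and 12.7 ± 0.568 CPM. DUSP4 (log2 -2.67, -2.30 and -2.55), SPRY4 (log2 -1.75, -1.49 and -1.88) and DUSP5 (log2 -1.40, -1.18 and -1.42), negative regulators of the pathway that it induces, fell too. Camera called this list down; with an estimated correlation the adjusted p was 0.0234, 0.055 and 0.0436, and 0.00731, 0.0179 and 0.00951 with the block as well.

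Many inflammatory cytokine genes of the NF-kB list fell, though the call of the list as a set was not stable. Of 18 tested members 10 fell in p63KO and 11 each in p73KO and dKO, and 0 rose (lower 10, 11 and 14 and higher 1, 1 and 0 adjusted over the list alone). Those higher by edgeR at an unadjusted p under 0.05 were 1, 1 and 0, and 0 rose by DESeq2; TNFAIP2 (log2 0.42, 0.41 and 0.25) passed with the replicate block in p63KO and p73KO. IL1A fell from 314 ± 90.5 CPM to 59.6 ± 24.8, 46 ± 21 and 30 ± 10.2 CPM, IL1B from 31.1 ± 7.75 to 1.91 ± 0.696, 1.44 ± 0.719 and 0.786 ± 0.252 CPM, and the prostaglandin synthase gene PTGS2 fell too (log2 -2.14, -3.10 and -3.51). Without p73KO replicate 1, 7 members fell in p73KO. The camera call (adjusted p = 1.48e-05, 3.13e-06 and 4.9e-08) was lost when the correlation was estimated: adjusted p = 0.346, 0.324 and 0.242 with an estimated correlation, and 0.158, 0.135 and 0.0946 with the block as well. Wound-edge keratinocyte genes went both ways: of 15 tested, 8, 7 and 8 fell and 4, 3 and 3 rose (lower 8 and higher 4 in each adjusted over the list alone; higher 5 in dKO with the replicate block). INHBA, an activin subunit, fell (log2 -2.22, -3.05 and -3.00) and the urokinase gene PLAU rose from 1.95 ± 0.458 to 12.5 ± 1.6, 9.56 ± 4.47 and 15.4 ± 1.56 CPM. In p63KO 2 members rose without NT replicate 1 or 3 or without p63KO replicate 2 or 3. Camera gave adjusted p = 0.0208, 0.0562 and 0.0473 (0.0236 in p73KO with the block), and adjusted p = 0.425, 0.534 and 0.509 with an estimated correlation.

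Many genes of the p53 target list fell and few rose. Of 30 tested p53 target genes, 16 fell and 2 rose in p63KO, 15 fell and 2 rose in p73KO, and 15 fell and 1 rose in dKO (lower 17, 16 and 19 and higher 2, 2 and 2 adjusted over the list alone; higher 2 in dKO with the replicate block). In p63KO 0 rose without NT replicate 2 or p63KO replicate 1 or 2. The antiproliferative gene BTG2 fell from 10.2 ± 0.645 CPM to 2.33 ± 0.28, 1.1 ± 0.506 and 1.75 ± 0.418 CPM, the maspin gene SERPINB5 from 99.6 ± 26.2 to 25.1 ± 8.07, 17.2 ± 6.87 and 9.68 ± 4.13 CPM, and the cell cycle inhibitor gene CDKN1A from 101 ± 2.22 to 43.7 ± 3.7, 28.1 ± 4.48 and 26.5 ± 0.601 CPM. SPATA18 (log2 -3.53, -4.68 and -4.06) and the death receptor gene EDA2R (log2 -2.03, -2.01 and -2.31) fell too. Camera called the list down with an estimated correlation as well (adjusted p = 0.0127, 0.00851 and 0.00413). p63 and p73 are known to act on many p53 targets, so the list does not single out p53.

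Targets of YAP and TEAD rose in large part. Of 23 tested, 13, 15 and 14 rose and 2 fell in each knockout (higher 14, 16 and 16 and lower 2, 2 and 3 adjusted over the list alone; lower 4 in dKO with the replicate block). TGFB2, which encodes transforming growth factor beta 2, rose from 1.2 ± 0.359 CPM to 15.3 ± 1.74, 17.7 ± 3.85 and 18.8 ± 2.59 CPM, CCN1 from 35.4 ± 11.5 to 136 ± 42.2, 152 ± 63.6 and 162 ± 57.3 CPM, and ANKRD1 by 2.58, 2.90 and 2.16 log2. The camera call (adjusted p = 7.4e-05, 1.29e-05 and 0.000443) was lost when the correlation was estimated: adjusted p = 0.312, 0.271 and 0.365 with an estimated correlation, and 0.0295, 0.0179 and 0.038 with the block as well.

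Proliferation genes showed small increases, and the number called without the replicate block changed when single libraries were left out. The fits with a library left out did not include the block. Of 26 tested, 4 rose in p63KO, 8 in p73KO and 4 in dKO, and 0 fell (0, 8 and 0 higher adjusted over the list alone; 12, 15 and 12 higher and 0 lower with the replicate block; edgeR gave 9, 11 and 6 a higher and 0 a lower level at an unadjusted p under 0.05, and DESeq2 called 4, 7 and 3 higher and 0 lower). In p73KO, the thymidylate synthase gene TYMS rose from 11.5 ± 0.726 to 46.3 ± 33.9 CPM (log2 2.01, SE 0.415, adjusted p = 0.0027), and E2F1, a transcription factor of the S phase genes, rose by 1.36 log2 (SE 0.26, adjusted p = 0.00158). TYMS shares its locus with ENOSF1 on the opposite strand, whose reads may be included. The count fell to 2 in p63KO without NT replicate 1 and to 0 without p63KO replicate 1 or 2. It fell to 5 in p73KO without NT replicate 1 and to 4 without p73KO replicate 2. In dKO it was 0 without NT replicate 1, 2 without NT replicate 2, 1 without dKO replicate 1 and 2 without dKO replicate 2 or 3. Camera gave adjusted p = 0.055, 0.0242 and 0.117 (0.0488 in p63KO with the block), and adjusted p = 0.581, 0.534 and 0.71 with an estimated correlation. Of 22 interferon response genes, 7, 7 and 5 rose and 0, 1 and 0 fell (higher 7, 8 and 5 and lower 1, 2 and 0 adjusted over the list alone; higher 11, 11 and 8 and lower 2, 2 and 0 with the block). Lower at an unadjusted p under 0.05 by edgeR were 2, 2 and 0, and DESeq2 called 0, 1 and 1 lower. IFITM1 rose from 3.02 ± 0.518 to 6.33 ± 1.01, 5.4 ± 0.597 and 5.71 ± 0.288 CPM. IFITM1 overlaps IFITM2 on the same strand, whose mean level was 4.1 times that of IFITM1 and whose reads may be included. Camera did not call this list (adjusted p = 0.0569, 0.105 and 0.092).

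**Figure D3:**
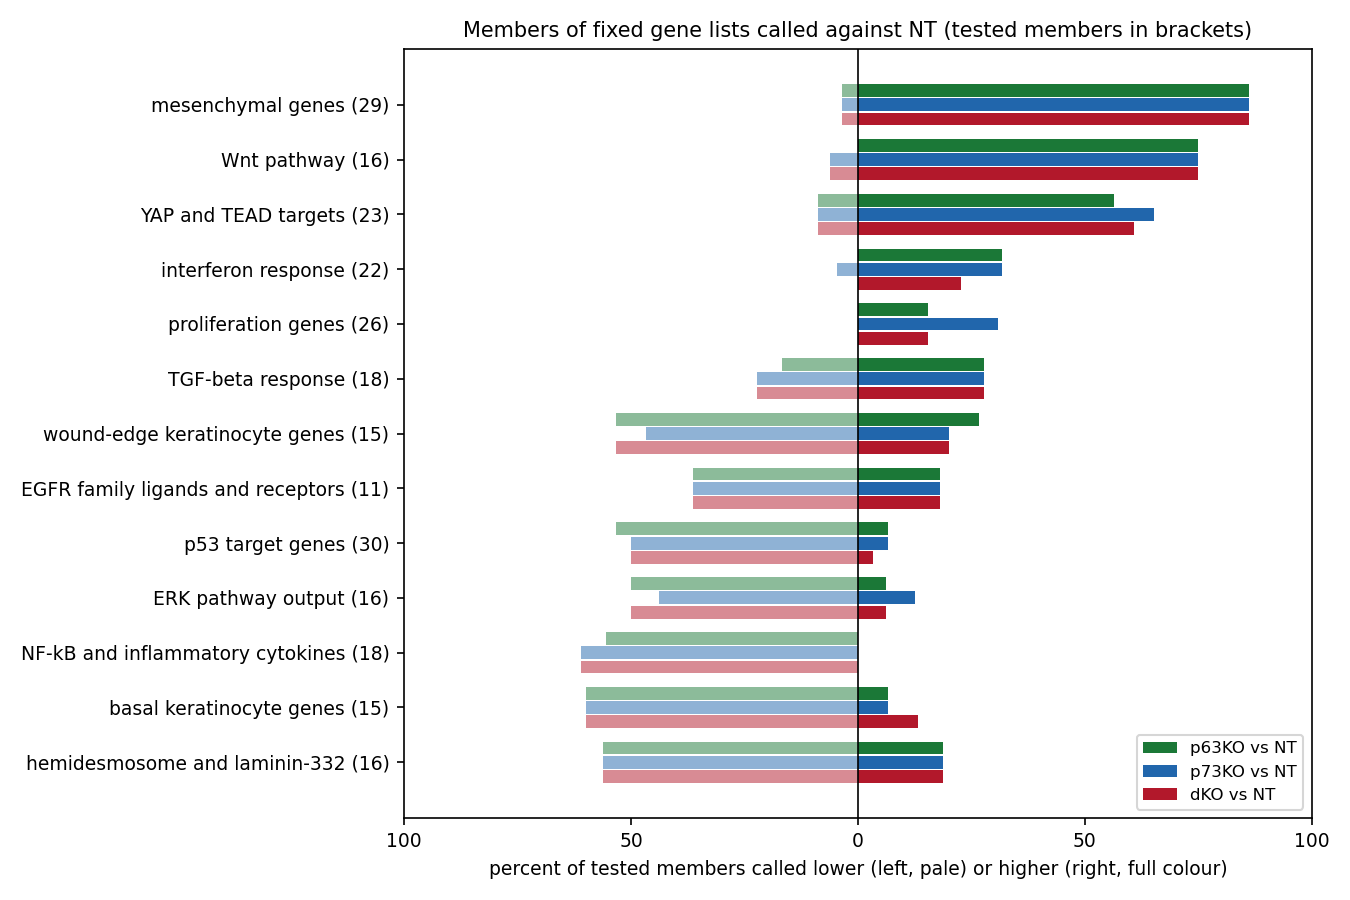
Percent of the tested members of 13 gene lists that were called lower (left, pale) or higher (right, full colour) in each knockout against NT by edgeR; the number of tested members is in brackets. Mesenchymal genes (25 of 29 higher in each knockout) and Wnt pathway genes (12 of 16) lie furthest to the right.

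The other lists were not called by camera in any knockout, apart from markers of other cell types in p63KO. TGF-beta response genes had 5 higher in each knockout and 3, 4 and 4 lower of 18 (higher 6, 5 and 5 and lower 6, 5 and 7 adjusted over the list alone; lower 7, 8 and 8 with the block); LTBP1, which holds latent TGF-beta, rose by 2.19, 2.04 and 2.61 log2 and ID1 fell (log2 -1.89, -1.90 and -2.19). The median of that list was negative (-0.0204, -0.148 and -0.0983) and its mean positive (0.246, 0.186 and 0.169), and camera's direction was up. Notch pathway genes had 1, 1 and 3 higher and 3, 2 and 2 lower of 12, the same counts adjusted over the list alone, with NOTCH3 higher (log2 1.60, 1.72 and 2.13) and HES1 lower (log2 -0.80, -1.12 and -1.11); with the block 3, 2 and 5 rose and 4, 4 and 5 fell, and 1 rose in dKO without NT replicate 1. Their median was positive (0.0557, 0.0123 and 0.175), camera's direction down and their mean -0.0986, -0.0298 and 0.0639. Hypoxia response genes had 4, 5 and 4 higher and 4, 4 and 3 lower of 21 (higher 4, 6 and 4 and lower 4, 5 and 3 adjusted over the list alone; higher 8, 10 and 7 with the block). CA9, a carbonic anhydrase gene, rose, with 2 counts in NT and ratios of 38.4 (10.3 to 322), 47.6 (12.8 to 399) and 56.5 (15.3 to 472); it overlaps another gene on the opposite strand, whose reads may be included. ANGPTL4 (log2 -2.71, -2.69 and -3.51) and PFKFB4 (log2 -2.11, -2.30 and -2.07) fell. The 5 higher in p73KO became 3 without NT replicate 1 or 3 or p73KO replicate 2 and 9 without p73KO replicate 3, and the 4 lower in p63KO became 2 without p63KO replicate 1. Cholesterol synthesis genes had 3, 5 and 2 higher and 2, 3 and 2 lower of 19 (higher 3, 7 and 2 and lower 2, 4 and 2 adjusted over the list alone; higher 8 in p73KO and lower 5 in p63KO with the block), with STARD4 higher (log2 0.81, 0.91 and 0.71) and SQLE lower (log2 -0.58, -0.74 and -0.72). The 3 higher in p63KO became 1 without NT replicate 1 or p63KO replicate 1 or 2, and the 5 higher in p73KO became 3 without NT replicate 1 or p73KO replicate 2 and 8 without p73KO replicate 3; the lower counts became 5 without p63KO replicate 3 and 1 without p73KO replicate 1. Their median was 0.0926, 0.325 and 0.09, their mean 0.0497, 0.189 and -0.00219, and camera's direction down in p63KO and dKO.

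Integrated stress and unfolded protein response genes had 1, 3 and 2 higher and 2, 4 and 2 lower of 21 (higher 0, 3 and 3 and lower 0, 4 and 5 adjusted over the list alone; higher 4, 4 and 3 and lower 4, 6 and 6 with the block). The chaperone gene HSPA5 fell in p73KO (log2 -0.66, adjusted p = 0.0064). It fell in p63KO as well, which was lost without NT replicate 1 or 2 or p63KO replicate 1 or 2 (0.0734, 0.089, 0.0758 and 0.122). SDF2L1, of the endoplasmic reticulum, fell in each knockout (log2 -0.85, -0.86 and -0.71). That was lost in p63KO and p73KO without NT replicate 3 (0.07 and 0.0582) or without replicate 1 or 2 of the knockout (0.0785 and 0.0803; 0.062 and 0.0591), and in dKO without NT replicate 1, 2 or 3 or dKO replicate 1 or 2 (0.0625 to 0.154). The lower count in p73KO was 2 without NT replicate 2 or p73KO replicate 1 or 2, and in dKO 0 rose without NT replicate 1 or 3 or dKO replicate 1. Their median was 0.008, 0.0493 and -0.0648 and their mean -0.0429, -0.0221 and -0.101. Epithelial and luminal genes had 1, 2 and 1 higher and 1 lower in each of 9 tested, the same counts adjusted over the list alone (higher 3, 4 and 2 with the block): the keratin gene KRT8 rose (log2 1.10, 0.94 and 1.03) and the splicing regulator gene ESRP1 fell (log2 -1.35, -1.98 and -1.47). KRT8 overlaps KRT18 on the opposite strand, whose mean level was 1.39 times that of KRT8 and whose reads may be included. The second higher call in p73KO, MUC1 (adjusted p = 0.0445), was lost without NT replicate 2 or 3 or p73KO replicate 1 or 2 (0.13, 0.149, 0.155 and 0.105) and by DESeq2 (0.0951), which left 1. The median of the list was 0.155, -0.016 and 0.0119, its mean 0.0677, -0.0185 and -0.05, and camera's direction was up in each. Multiciliated cell genes had 1 of 7 higher in each, also adjusted over the list alone, the dynein gene DNAH5 (log2 1.45, 1.36 and 1.31), and 0 lower by edgeR and by DESeq2 (2, 1 and 1 lower and, in dKO, 2 higher with the block; 1, 0 and 0 lower at an unadjusted p under 0.05 by edgeR). Their median was -0.225, -0.208 and -0.265 and their mean -0.00251, 0.149 and 0.2. Mitochondrially encoded genes had 0 of 13 called by edgeR in each knockout, also adjusted over the list alone and by DESeq2 in p63KO and p73KO, with 0, 1 and 1 at an unadjusted p under 0.05; with the block 2 rose in p63KO, 6 fell in p73KO and 4 fell in dKO, and 1 fell in dKO by DESeq2. Of 16 markers of other cell types 4 were tested: 1 rose in each knockout, and 3, 2 and 2 fell, the same counts adjusted over the list alone. PTPRC, a leukocyte gene, had 3 counts in NT and ratios of 23.3 (7.67 to 116), 22.9 (7.5 to 114) and 44.6 (15 to 219). Its call was lost in p63KO without NT replicate 1 or 2 or p63KO replicate 2 (adjusted p 0.0525, 0.0538 and 0.0744) and in p73KO without p73KO replicate 2 (0.0648). PDGFRA and DCN fell in each knockout, and CD68 fell in p63KO, which was lost without NT replicate 2 or 3 or p63KO replicate 2 (0.0616, 0.132 and 0.122). Camera called these markers down in p63KO (adjusted p = 0.0208), which was lost with the block (0.0976) and with an estimated correlation (adjusted p = 0.198).

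The effects of the knockouts were much alike. Of the genes called against NT, 1580 rose and 1269 fell in all 3 knockouts, 2849 of the 5716 called in at least 1; with the replicate block 4790 were called in one direction in all 3. p63KO and p73KO shared 1798 higher and 1474 lower calls, where independent comparisons would share 379 and 267, and had 0 in opposite directions by edgeR and by DESeq2 (1 at an unadjusted p under 0.05 in both). p63KO and dKO shared 1695 and 1386 (313 and 217 if independent) with 3 opposite, and p73KO and dKO shared 1838 and 1459 (357 and 247 if independent) with 0 opposite by both tools (1 at an unadjusted p under 0.05 in both). In simulated unchanged groups with the same shared controls, edgeR gave 0 shared calls in either direction. Log2 fold changes correlated across genes, which are not independent replicates, at 0.948, 0.94 and 0.951 in these 3 pairs, against means of 0.497, 0.502 and 0.498 in the simulations. Their covariances were 0.75, 0.768 and 0.799 against simulated means of 0.0296, 0.0296 and 0.0296. The simulations include the shared controls, and their highest covariances were 0.0329, 0.0311 and 0.0317. A difference of the NT line itself is not in the simulations and may be part of the excess. Without the low-count filter, the correlations were 0.657, 0.657 and 0.666.

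**Figure D4:**
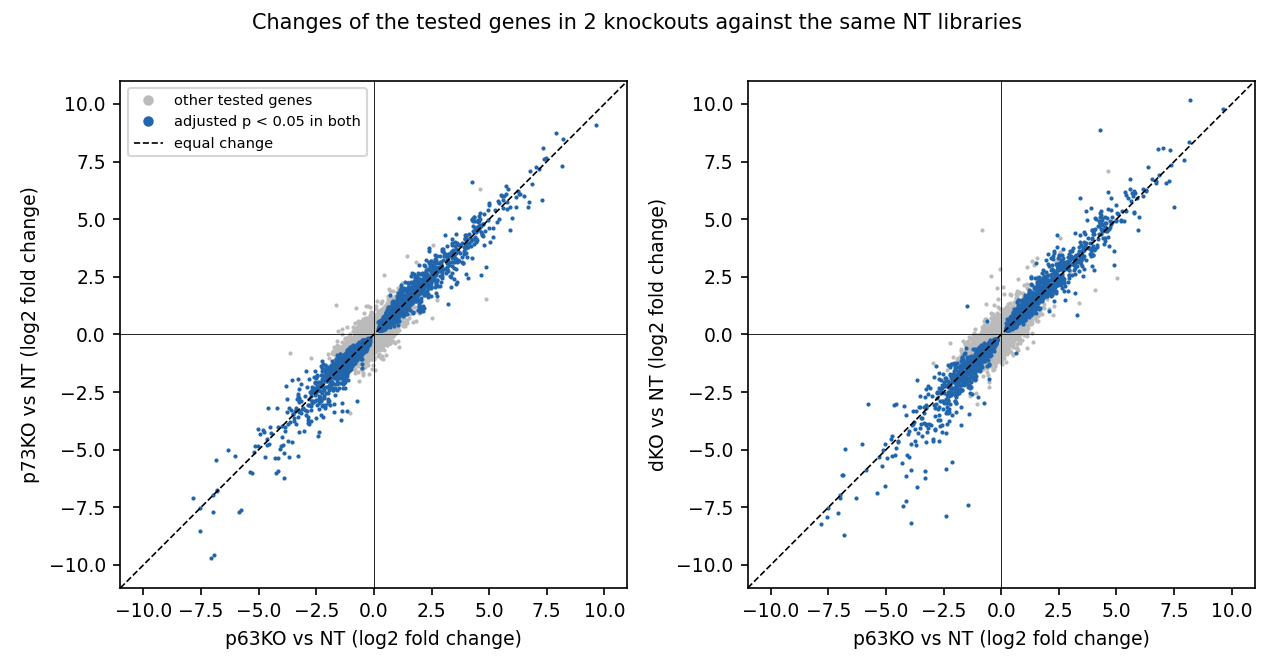
Log2 fold changes of 14754 tested genes in p73KO (left) and dKO (right) against those in p63KO, all against the same NT libraries; blue points were called in both and the dashed line marks equal change. Points lie along the line, with correlations of 0.948 and 0.94 across genes.

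Among the 3272 genes called in the same direction in both single knockouts, the log2 change in dKO was 0.981 times the mean of the single changes at the median gene (quartiles 0.84 and 1.11), where adding the effects would give 2. Among the 1291 of these with a mean change of at least 2-fold the median ratio was 1.03 (quartiles 0.916 and 1.14). The change in p73KO was 1.03 times that in p63KO at the median gene (quartiles 0.893 and 1.21). A difference of the NT line alone would also make these changes alike, and each single knockout had lost most of both transcripts.

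What p73 loss adds to p63 loss was asked by dKO against p63KO. The TP73 transcript was already at 22.3% of NT in p63KO and stood at 19.1% in dKO. Little further loss of the transcript was thus compared. Whether p73 protein differed between the 2 groups cannot be seen from counts. TIMP3, an inhibitor of matrix metalloproteinases, rose 2.24-fold from 148 ± 1.65 CPM (log2 1.16, SE 0.118, adjusted p = 0.000506); it stood at 33.4 ± 4.68 CPM in NT. ALDH1A1 fell from 6.39 ± 1.07 to 0.754 ± 0.29 CPM (log2 -3.09, SE 0.29, adjusted p = 0.000336), and CUX2 (log2 -2.94) and ENKUR (log2 -2.92) fell with an adjusted p of 0.00202 each. TP73 and ITGB4 differed by -0.20 (SE 0.219) and -0.17 (SE 0.346) log2 and did not pass. TP63 differed by -1.02 log2 (SE 0.348, adjusted p = 0.464), and by -1.01 with the replicate block, where it passed (adjusted p = 1.58e-05). Of the 14754 genes 61 were called, 27 higher and 34 lower, and 519 with the block; 968 had an unadjusted p under 0.05. All 61 were also called against NT in at least 1 knockout. The count was 35 and 29 without p63KO replicates 1 and 2, and 31, 33 and 28 without dKO replicates 1, 2 and 3. FAM133A rose by 1.18 log2, which was lost without p63KO replicate 1, 2 or 3 or dKO replicate 2 or 3 (0.0536 to 0.0875). SEMA3B rose by 1.14, lost without p63KO replicate 1 or 2 or dKO replicate 1, 2 or 3 (0.0504 to 0.0711). ANXA8, which may share reads with ANXA8L1, fell by 3.40, lost without p63KO replicate 1 or 2 or dKO replicate 1, 2 or 3 (0.11 to 0.172).

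What p63 loss adds to p73 loss was asked by dKO against p73KO. The TP63 transcript was already at 14.6% of NT in p73KO and stood at 12.6% in dKO. Little further loss of the transcript was thus compared. Whether p63 protein differed between the 2 groups cannot be seen from counts. TIMP3 rose 4.92-fold from 67.5 ± 9.37 CPM (log2 2.30, SE 0.123, adjusted p = 1.51e-06). EDIL3, an extracellular matrix gene, rose by 1.34 log2 (adjusted p = 0.00379). NLGN4X, a cell adhesion gene, fell from 7.59 ± 1.14 to 2.16 ± 0.351 CPM (log2 -1.80, SE 0.184, adjusted p = 0.00141), and the actin-binding gene SYNPO2 fell by 1.66 log2 (adjusted p = 0.00141). TP63, TP73 and ITGB4 differed by -0.21 (SE 0.351), -0.55 (SE 0.215) and -0.63 (SE 0.344) log2 and did not pass. Of the 14754 genes 18 were called, 10 higher and 8 lower, and 252 with the replicate block; 910 had an unadjusted p under 0.05. All 18 were also called against NT in at least 1 knockout. The count was 7, 9 and 10 without p73KO replicates 1, 2 and 3, and 11, 6 and 6 without dKO replicates 1, 2 and 3. COL6A1 rose by 1.14 log2, which was lost without p73KO replicate 1 or 2 or dKO replicate 2 or 3 (adjusted p 0.0527 to 0.0723). SLC2A9 fell by 1.02, lost without any 1 of the 6 libraries (0.0635 to 0.158), and FRMD4B fell by 0.71, lost without p73KO replicate 1 or 3 or any 1 dKO library (0.0723 to 0.14).

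The single knockouts were compared with p63KO against p73KO. CD82, a tetraspanin gene, stood at 39.2 ± 3.07 CPM in p63KO and 8.91 ± 1.16 CPM in p73KO (log2 2.14, SE 0.175, adjusted p = 0.000168) and at 65.3 ± 11.5 CPM in NT. GUCY1A2, a guanylate cyclase subunit gene, stood at 96.3 ± 16.7 and 24.6 ± 6.24 CPM (log2 1.97, SE 0.17, adjusted p = 0.000168), and SYT11 was lower in p63KO by 0.99 (log2 -0.99, SE 0.102, adjusted p = 0.000989). TP73 and ITGB4 differed by -0.34 (SE 0.213) and -0.46 (SE 0.343) log2 and did not pass. TP63 was 0.81 log2 higher in p63KO than in p73KO (SE 0.347, adjusted p = 0.468), and 0.80 with the replicate block, where it passed (adjusted p = 0.000203). Of the 14754 genes 34 were called, 22 higher and 12 lower in p63KO, and 465 with the block; 1458 had an unadjusted p under 0.05. All 34 were also called against NT in at least 1 knockout. The count was 11, 11 and 19 without p63KO replicates 1, 2 and 3, and 13 and 16 without p73KO replicates 1 and 2. ENKUR was 1.98 log2 higher in p63KO, lost without p63KO replicate 1 or 2 or any 1 p73KO library (adjusted p 0.0572 to 0.14), and SMOC1 1.93 higher, lost without p63KO replicate 1 or 2 or p73KO replicate 1 or 3 (0.0822 to 0.15). GALNT15 differed by -1.26, lost without p63KO replicate 1, 2 or 3 or p73KO replicate 2 or 3 (0.0637 to 0.171), NLGN4X by -1.23, lost without p63KO replicate 1 or 3 or p73KO replicate 2 (0.0586 to 0.0802), and CAPG by -0.89, lost without any 1 of the 6 libraries (0.0597 to 0.215).

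Whether the effect of losing both genes differs from the sum of the single effects was tested by the interaction. ITGB4 had an interaction of 3.87 log2 (SE 0.491, adjusted p = 0.000151): its log2 changes were -4.50 and -4.04 in the single knockouts and -4.67 in dKO, so the double knockout lay above the sum. TGFA (7.60, SE 0.384, adjusted p = 1.1e-07), PPP1R14C (8.15, SE 0.831) and PLCH2 (6.72, SE 1.17) did likewise. In p63KO, p73KO and dKO, PPP1R14C held 9, 4 and 7 counts, PLCH2 13, 20 and 10, and TGFA 41, 23 and 39. At so few counts little room was left for a further fall, so these values say little about how the losses combine. COL5A3, which rose in each knockout, lay below the sum (-6.47, SE 0.754, adjusted p = 7.36e-05). CSF3 was above the sum (adjusted p = 0.000291) and MSTN (9.52e-06), APCDD1 (1.4e-05) and CMKLR1 (0.0153) below it; these have 0 to 3 counts in a group, so the size is not given. The interaction was 1.62 log2 for TP73 (adjusted p = 0.0022) and 1.76 for TP63 (adjusted p = 0.0277). The call of TP63 was lost without NT replicate 1 or 2, p63KO replicate 1, p73KO replicate 1 or dKO replicate 1 or 2 (adjusted p 0.0505 to 0.0695). Of the 14754 genes 2320 were called, 990 above and 1330 below the sum, and 5403 with the replicate block. Of the 990, 885 were lower in both single knockouts, and of the 1330, 1232 were higher in both. A difference of the NT line from all 3 edited lines would by itself give an interaction of that size.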

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

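The tests of explanations in this part were all chosen after the result was seen; the interaction and the regroupings of libraries were set before the data were examined.

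The change on p63 loss differed with and without p73 loss, by the interaction test, in 2320 genes. A difference of the NT line from all 3 edited lines would by itself give such interactions. The test alone therefore does not show a dependence on p73. The interaction was 1.76 log2 for TP63, 1.62 for TP73 and 3.87 for ITGB4. The call of TP63 was lost without NT replicate 1 or 2, p63KO replicate 1, p73KO replicate 1 or dKO replicate 1 or 2 (adjusted p 0.0554, 0.0694, 0.0542, 0.0667, 0.0505 and 0.0695). The interaction was 8.15 for PPP1R14C, 7.60 for TGFA, 6.72 for PLCH2 and -6.47 for COL5A3. PPP1R14C, TGFA and PLCH2 had few counts in each knockout, which left little room for a further fall. CSF3 (adjusted p = 0.000291), MSTN (9.52e-06), APCDD1 (1.4e-05) and CMKLR1 (0.0153) were called too, with 0 to 3 counts in a group and hence no size. Among 100 splits of the 12 libraries into 4 groups of 3, the real one included, 2 called as many genes as the real 2320. That share reflects how seldom a random split keeps NT together: 3 others that kept the NT libraries in 1 group called 1470 to 2581, 1 of them more than the real split, and the 96 that parted them called at most 15, with 95 at 0. The splits ignored the pairing by number, and they were sorted by NT after their counts were seen, so they do not exclude chance for the grouping of the 9 edited libraries. In these splits the count followed whether the NT libraries were kept together.

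Of the 5716 genes called in at least 1 knockout, 2849 were called in one direction in all 3 and 3 in both directions. Shared NT libraries do not account for all of this likeness: the covariance of the p63KO and p73KO changes was 0.75, above the highest of 20 simulations of unchanged groups (0.0329). A difference of the NT line from the edited lines that does not depend on the gene cut cannot be told apart from the knockout effects, because there is 1 non-targeting line, and it could account for the 2849 genes. A candidate biological explanation is that p63 and p73 are both needed for one program. The change in dKO was 0.981 times the mean of the single knockouts at the median gene, where added effects give 2. This ratio cannot decide the question, since a difference of the NT line alone would give a ratio near 1. Each single knockout had also lost most of both transcripts: TP73 stood at 22.3% of NT in p63KO and TP63 at 14.6% in p73KO. In dKO they stood at 19.1% and 12.6%. That both genes are needed is a hypothesis found in the same data. A second non-targeting line would test the difference of the NT line, and could not by itself show a need for both genes.

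TP63 and TP73 transcripts remained in their own knockouts, at 25.5% and 28.2% of NT by the fitted change. If unedited cells with NT levels of every transcript were the whole source, every gene would lie at or above those percentages. Yet 112 genes in p63KO and 145 in p73KO lay below by more than 2 SE. Of these, 51 and 65 had at least 10 CPM in NT, and 30 and 39 lay under 5% of NT. The SE are those of each gene and leave out the error of TP63 and TP73 themselves (SE 0.346 and 0.195 log2). Unedited cells may still be the source of a part. Transcripts with a frameshift that escape decay may be the source of the 25.5% of TP63, and this stays open because gene counts carry no read sequence. By mean CPM, TP63 stood at 14.6% of NT in p73KO and TP73 at 22.3% in p63KO, where each was not the target. The fall of each transcript in its own knockout therefore need not come from its editing. Some of the TP73 counts may also be reads of WRAP73 on the opposite strand, which was not tested.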

How the results depend on the processing

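Leaving out the libraries numbered 3, the block with an estimated correlation, and the DESeq2 correlation over genes with an adjusted p were chosen after the data were seen; the other alternatives were set before. No result changed direction and passed under any alternative run. RLE size factors and the robust prior left the count of calls of each comparison within 1.5 times its value and every correlation between knockouts within the spread between libraries left out; of the list counts 1 moved by more, ERK output higher in p73KO, from 2 to 1 with RLE.

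With an adjusted p under 0.01, stricter by construction, the calls were 2387 in p63KO, 2683 in p73KO and 2352 in dKO against NT, 29 in dKO against p63KO, 6 in dKO against p73KO, 10 in p63KO against p73KO, 1093 for the interaction and 1730 in all 3 knockouts. With the replicate block they were 6792, 7142, 6351, 519, 252, 465, 5403 and 4790 in the same order, with a coefficient of variation of 6.79% in place of 12.4%. Among the 305 results of genes named by the rule the block changed 2 calls, those of TP63 in dKO and in p73KO against p63KO, and among 66 set tests of lists it changed 6. Of genes named outside the rule, SNAI2 in each knockout, FZD8 in p63KO and TNFAIP2 in p63KO and p73KO passed with it and not without. Between knockouts, in the order dKO against p63KO, dKO against p73KO and p63KO against p73KO, the calls were 265, 178 and 233 without the low-count filter and 133, 63 and 112 by DESeq2; the cause was not tested. A fit of the 2 compared groups, which has fewer libraries, gave 5 in dKO against p73KO and 6 in p63KO against p73KO.

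Leaving out 1 library at a time gave 2884 to 4217, 3407 to 4957 and 2839 to 3374 calls against NT, 28 to 50, 6 to 11 and 11 to 25 between knockouts, 1584 to 3111 for the interaction and 2334 to 2714 in all 3. Leaving out the libraries numbered 3 from every group gave 4315, 4918, 3763, 71, 17, 36, 2934 and 2903. Among those 305 results, 17 calls were lost without the libraries numbered 3, 16 with the 2 compared groups only, 51 at an adjusted p under 0.01, 5 by DESeq2, 3 without the filter (which added 4), 2 with the robust prior and 1 with RLE. Of the 66 list results, 18 calls were lost with an estimated correlation and 7 with the block as well, and fry added 15.

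The correlations between knockout effects (p63KO with p73KO, p63KO with dKO, p73KO with dKO) were 0.657, 0.657 and 0.666 without the filter and 0.715, 0.715 and 0.725 by DESeq2, both of which bring in genes with few counts. They were 0.916, 0.911 and 0.91 by DESeq2 over genes with an adjusted p, 0.97, 0.962 and 0.97 over called genes only, and 0.932 and 0.938 for the first and last pair without the libraries numbered 3. With 1 library left out they ran from 0.932 to 0.949, 0.916 to 0.943 and 0.921 to 0.951. Depth limits genes with 0 to 3 counts in a group, for which ratios are bounds or carry wide intervals.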

Other observations

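The tests of library totals and the choice of genes came after the result was seen. So did the comparison of the libraries numbered 3 with the others. The prediction on growth state and the splits of the libraries were written before. The growth-state test used that comparison of the libraries numbered 3, so its contrast was chosen after the result was seen.

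The libraries numbered 3 differed from those numbered 1 and 2 in every group. With the group as a term in the model, 5336 genes were called, 2602 higher and 2734 lower in number 3, of which 226 changed at least 2-fold. The clock gene CRY1 (log2 1.27) and TXNIP (0.80) were higher, and ANXA2 (-0.82), the phosphodiesterase gene PDE4D (-1.12) and EGR1, an immediate early gene (-1.65), were lower. NF-kB cytokine genes (13 of 18 lower) and YAP and TEAD targets (16 of 23 lower) were called down by camera (adjusted p = 5.2e-08 and 7.49e-07), calls that were lost with an estimated correlation (adjusted p = 0.28 and 0.217). Camera also called down basal keratinocyte and integrated stress genes (adjusted p = 0.00576 each) and ERK output, wound-edge, proliferation and mitochondrially encoded genes (0.00992 each), and these were lost with an estimated correlation too (0.217 to 0.454).

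Library totals do not account for this: in 1 group, NT, number 3 had neither the highest nor the lowest total, and it had the lowest in p63KO and the highest in p73KO and dKO. A shared difference in growth state of the cultures may be the source and stays open: the median of proliferation genes was -0.268 log2 (15 of 26 lower, 2 higher), and their call by camera (adjusted p = 0.00992) was lost with an estimated correlation: the lowest camera adjusted p of the proliferation, cholesterol and hypoxia lists was then 0.378. The labels give no batch or day, so one cannot be told apart from growth state.

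Among genes called in both p63KO and dKO against NT, 3 went in opposite directions: FAM133A (log2 -0.61 and 0.57, adjusted p 0.0328 and 0.0397), ARHGAP44 (-1.49 in p63KO and higher in dKO, 0.0452 and 0.0288) and LINC01029 (0.65 and -0.79, 0.0463 and 0.031). They were named after their values were seen, and their calls against NT were not recomputed with single libraries left out.

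Comparisons that share no library can be set side by side without the problem of shared controls. The effect of p63 loss against NT and its effect on p73KO cells (dKO against p73KO) correlated across genes at 0.0707, with a covariance of 0.0178 (simulated highest 0.00207); 9 genes were higher and 4 lower in both (1.5 and 1.01 if independent) and 3 went in opposite directions. For p73 loss, against NT and on p63KO cells, the correlation was 0.169 and the covariance 0.0484 (simulated highest 0.00108), with 17 higher and 26 lower in both (4.62 and 4.87 if independent) and 5 opposite. In the simulations edgeR gave 0 shared calls in either direction. Simulated genes varied independently of each other, so the highest simulated covariances may be too low a bound for correlated genes. These small correlations can therefore not be told apart from shared variation between libraries.

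The 6 libraries of 2 groups can be split in 10 ways, too few for a share under 0.05, and 1 of the 10, the real split, gave as many calls in each comparison. The real values were 4073, 4638 and 3809 against NT and 61, 18 and 34 between knockouts; the highest of the other splits was 1 in dKO against p73KO and 0 in the rest by edgeR. At an unadjusted p under 0.05 the highest of the others was 1412, 1657 and 974 against NT (real 5758, 6134 and 5433). Between knockouts it was 2423, 2402 and 2368 (real 968, 910 and 1458), so another split holds more genes than the real one there, which points to the structure by replicate number. Of the 9 other splits, 3 part all 3 pairs of equal number and called at most 1 gene, and 6 part 1 pair and called 0.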
